A study of Mus musculus with 4 samples.

How the data were processed

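RNA from 2000 sorted mouse bone marrow cells per library was turned into cDNA and amplified with the SMARTer kit and sequenced on an Illumina platform, per the labels' protocols. The submitters' processing notes name TopHat, with no version, and the mm9 genome build. The read counter, the gene annotation, the treatment of duplicate and shared reads and any filter are not given in the sources used here. Each of the 4 deposited files, 1 per library, lists 23450 gene symbols with a value on a log2 scale made by the authors. The steps between low values show whole numbers of reads scaled by a library total to CPM, a rate per fixed number of library reads. The log2 value was taken as that of the number of reads plus 1. Raising genes without a read to 1 read would give the same steps, which cannot tell these readings apart. Each read gene would then hold 1 read more than given here, and a gene without a read could hold 1. Every value standing for at most 100 reads came out within 0.1 of a whole number of reads (100% of 12812 to 13135 values per library). These values include genes without a read, which are whole by construction, and the scale was set from the same steps. The reads recovered in this way, 13064913, 16145191, 15032001 and 14824549 in LT-HSC 1, LT-HSC 2, ST-HSC 1 and ST-HSC 2, fell short of the authors' totals by 0.116%, 0.0853%, 0.0907% and 0.0921%. A floor of 3 reads in a library equals 0.229, 0.186, 0.199 and 0.202 CPM in the same order. No genome coordinates are given, because the annotation at hand is of another build.

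The groups were taken from the labels, 2 libraries each, and LT-HSC against ST-HSC is the only comparison. A positive log2 fold change means higher in LT-HSC. The main test had been planned for raw counts. Because the deposited values are on a log2 scale, the test planned for normalized values was used. CPM were computed from the log2 values by undoing the read taken as added, with the authors' library totals as the only scaling. Genes with at least 1 CPM in at least 2 libraries were kept (12569), and log2(CPM + 1) was tested with limma 3.58.1 in R 4.3.3 (trend and robust shrinkage with statmod 1.5.0). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. Means ± SD are of CPM over the 2 libraries of a group, and an SE belongs to the log2 fold change in the limma fit.

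Gene lists were tested with limma's camera, 2-sided, with a preset correlation between genes of 0.01, adjusted over the 31 lists with at least 5 tested members. Calls were set beside camera with an estimated correlation and beside fry, which asks whether a list's genes move on balance 1 way. None of the 31 lists passed with the estimated correlation, which also missed a shifted list in each of 10 simulated runs (below). The estimate was 0.0869 for S phase, 0.0231 for G2/M phase, 0.0388 for HSC-associated and -0.0409 for immediate early genes. Where the correlation exceeds the preset 0.01, p-values with the preset can be too small. Each list's median was also placed among 10000 random lists of the same size matched on mean expression. The lists cover HSC-associated, progenitor and lineage genes, cell cycle phases, quiescence, imprinted, interferon, immediate early, heat shock, metabolic, surface and signalling genes, histone genes and mitochondrially encoded genes. The groups, lists, tests, threshold, most alternatives and the rule for named genes were fixed before the data were examined.

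The rule names the genes of the sort markers, up to 10 genes per direction with the largest fold change past the threshold, and for each list its members past the threshold, or else up to 2 members with the smallest p. It adds up to 5 genes per direction with the smallest p where fewer than 10 pass. Gene models without a name were left out, and some genes that the rule names are not reported here. Members past the threshold adjusted over a list alone are also named. Procr, which the rule names among the receptors, is given with the HSC-associated genes, and Mki67 and Cdkn1c were chosen after their values were seen.

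The alternatives were other scaling factors, other filters, another added value, thinning to the smallest library, the replicate number as a block, leaving out each library in turn, limma-voom on the recovered reads, no robust shrinkage, a looser threshold and other list tests. Added after the values were seen were TMM factors, the deposited log2 values as they are, a filter on mean log2(CPM + 1) of at least 5 and camera on ranks. The chi-square statistic of recovered reads over its degrees of freedom was 195.5 within LT-HSC and 149.0 within ST-HSC, so no library was counted as a copy of another. The gene test was tested on simulated reads for 12569 genes with the 4 library sizes and a squared coefficient of variation of 0.0767, in 10 runs with 200 changed genes each. It called 93% of the genes changed 4-fold and 100% of those changed 16-fold, with 11.3 false calls per run. In 10 simulated runs with the S phase list shifted by -1 on the log2 scale, camera called the list in 10 with the preset correlation and in 0 with the estimated one, and in 10 runs without a shift it called 0 lists. The simulated genes were independent of each other and varied alike, which real genes need not do. Their spread was the median of well covered genes, and changes were set only in genes well above the filter. Many real genes varied more, with 1188 cases of 100 or more reads in 1 library and 0 in the other of its group. The 93% therefore does not hold for the real data, where 0 calls do not exclude 4-fold changes.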

Results

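Transcript abundance was measured by RNA sequencing in hematopoietic stem cells (HSCs) sorted from mouse bone marrow. There were 2 libraries of long-term HSCs (LT-HSC), negative for CD48 and CD34, positive for CD150 and high for the tetraspanin CD9, and 2 libraries of short-term HSCs (ST-HSC), negative for CD48, positive for CD150 and low for CD9. No CD34 gate is given for the ST-HSC. Each library came from 2000 cells. Reads recovered from the deposited values numbered 13064913 in LT-HSC 1, 16145191 in LT-HSC 2, 15032001 in ST-HSC 1 and 14824549 in ST-HSC 2. Of 23450 listed genes, 14548 had a read in LT-HSC 1, 13341 in LT-HSC 2, 13318 in ST-HSC 1 and 13275 in ST-HSC 2. If the values are not reads plus 1 (above), genes with 1 read are counted here as unread. Across genes, the Pearson correlation of log2(CPM + 1) was 0.736 between the LT-HSC libraries and 0.797 between the ST-HSC libraries, against 0.714 to 0.763 between libraries of different groups. Genes are not independent replicates, and these correlations describe the libraries only.

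The single comparison asked how the transcripts of CD9-high, CD34-negative HSCs differ from those of CD9-low HSCs. Genes of the S and G2/M phases of the cell cycle fell as lists in LT-HSC, with median log2 fold changes of -1.16 and -1.46 (limma camera adjusted p = 3.21e-16 and 2.00e-16, and adjusted p = 0.443 for both with an estimated correlation). Genes associated with HSCs and immediate early genes, which respond fast to signals and to cell handling, rose as lists, with medians of 0.52 and 0.39 (adjusted p = 1.25e-08 and 0.0278, and adjusted p = 0.443 and 0.592 with an estimated correlation). Under fry, another limma test, the immediate early genes passed (adjusted p = 0.0343), while the G2/M phase, S phase and HSC-associated genes did not (adjusted p = 0.166, 0.195 and 0.195). No single gene passed the test over all genes. Of 12569 genes tested by limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.716. At an unadjusted p under 0.05 by limma there were 361 higher and 453 lower genes, 814 in all. Splitting the libraries by their number instead gave 735, and the remaining split into 2 and 2 gave 475. With limma-voom on the recovered reads, 0 genes passed the threshold and 586 the unadjusted one. The balance of the unadjusted counts turned on single libraries, with 186 higher and 622 lower without LT-HSC 1, 227 and 889 without LT-HSC 2, 407 and 153 without ST-HSC 1, and 286 and 129 without ST-HSC 2. Both LT-HSC libraries lay above both ST-HSC libraries for 16.2% of genes and below both for 17.5%, where chance alone gives 16.7% in each direction. Fold changes of single genes below are therefore values, not calls.

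The genes of the sort markers were read first. Cd9 stood at 129 ± 6.70 CPM (SD, n = 2) in LT-HSC and 106 ± 8.71 CPM (SD, n = 2) in ST-HSC, a log2 fold change of 0.28 ± 0.29 (SE). Slamf1, which encodes CD150, had a log2 fold change of 0.56 ± 0.38 (SE). Cd34 was at 168 ± 47.1 CPM in LT-HSC and 377 ± 74.7 CPM in ST-HSC (SD, n = 2 each), a log2 fold change of -1.18 ± 0.30 (SE). Cd48 had 2 reads in each LT-HSC library and 247 and 575 reads in the ST-HSC libraries, although both gates exclude the protein. The adjusted p was 0.955 for Cd9, 0.871 for Slamf1 and 0.716 for both Cd34 and Cd48.

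The list of G2/M phase genes, which act in chromosome segregation and mitosis, fell in LT-HSC. The median log2 fold change of its 55 tested members was -1.46, and 39 of them lay below both ST-HSC libraries while 1 lay above both (limma camera adjusted p = 2.00e-16, and adjusted p = 0.443 with an estimated correlation). Adjusted over the list alone, 1 gene passed, Top2a (topoisomerase II alpha), at 106 ± 16.3 CPM in LT-HSC and 482 ± 138 CPM in ST-HSC (SD, n = 2 each), against 0 over all genes. Hmmr, a spindle protein gene, had a log2 fold change of -5.17 ± 1.03 (SE). Mki67, which encodes the proliferation marker Ki-67 and was chosen after its values were seen, stood at 37.9 ± 28.8 CPM in LT-HSC and 206 ± 23.0 CPM in ST-HSC (SD, n = 2 each). The S phase genes, which act in DNA replication, also fell as a list. The median over 44 members was -1.16, with 30 below both ST-HSC libraries and 0 above both (adjusted p = 3.21e-16, and adjusted p = 0.443 with an estimated correlation). Adjusted over the list alone, 4 genes passed, all lower, against 0 over all genes. They included Nasp (a histone chaperone, log2 fold change -2.48 ± 0.34 SE), Rpa2 (a subunit of the single-strand DNA binding complex, -1.82 ± 0.30 SE) and Mlf1ip (a centromere protein gene, -2.10 ± 0.39 SE). Between libraries of the same number, the list medians were -1.02 and -1.41 for G2/M and -1.15 and -1.08 for S phase. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had a median of 0.16 over 62 members and did not pass (adjusted p = 0.172), except by camera on ranks (adjusted p = 0.00705). The histone median was 0.36 for libraries numbered 1 and -0.07 for those numbered 2, and ranged from 0.04 without LT-HSC 1 to 0.28 without LT-HSC 2. Many of these genes are near-identical copies, so their values are uncertain.

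**Figure D1:**
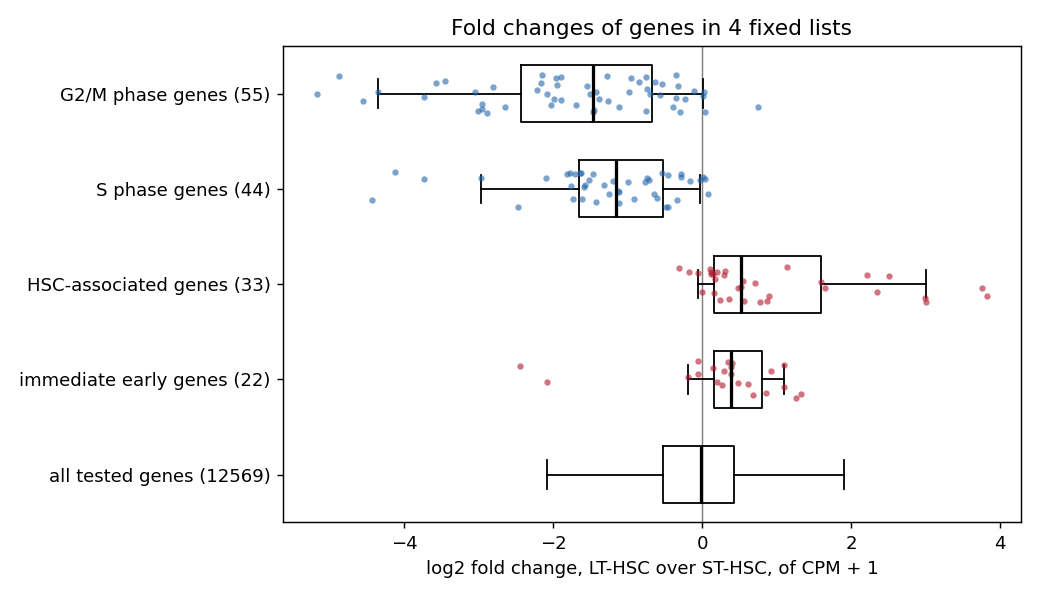
Log2 fold changes of CPM + 1, LT-HSC over ST-HSC, for the tested members of 4 gene lists and for all tested genes, with the number of genes in brackets. Each point is a gene, the box spans the quartiles with the median as a thick line, and the whiskers reach the 5th and 95th percentiles. The medians are -1.46 for G2/M phase, -1.16 for S phase, 0.52 for HSC-associated and 0.39 for immediate early genes.

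The list of HSC-associated genes rose in LT-HSC. Its 33 members had a median log2 fold change of 0.52 (0.34 with mean log2(CPM + 1) of at least 5), with 19 above both ST-HSC libraries and 1 below both (adjusted p = 1.25e-08, and adjusted p = 0.443 with an estimated correlation). No member passed adjusted over the list alone (smallest adjusted p = 0.0878), nor over all genes, where limma gave 0. Mecom, a transcription factor gene needed for HSC maintenance, stood at 768 ± 108 CPM in LT-HSC and 422 ± 80.9 CPM in ST-HSC (SD, n = 2 each). Sult1a1, a sulfotransferase gene, had a log2 fold change of 1.65 ± 0.42 (SE). Procr, which encodes the HSC surface marker EPCR, had 1.15 ± 0.29 (SE), and Cdkn1c, which encodes the CDK inhibitor p57, had 1.60 ± 0.70 (SE). Cdkn1c was chosen after its values were seen. Between libraries of the same number the list median was 0.73 and 0.42. The immediate early genes rose as a list, with a median of 0.39 over 22 members, 10 above both ST-HSC libraries and 2 below both (adjusted p = 0.0278, and adjusted p = 0.592 with an estimated correlation). The call for immediate early genes also ended without LT-HSC 1 (median 0.28, adjusted p = 0.0622) and with no filter on low values (median 0.37, adjusted p = 0.104). No immediate early gene passed adjusted over the list alone. Egr1, a transcription factor gene of this class, was at 483 ± 4.49 CPM in LT-HSC and 302 ± 29.4 CPM in ST-HSC (SD, n = 2 each), and Socs3, a feedback inhibitor of cytokine signalling, had a log2 fold change of -2.44 ± 1.0 (SE).

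The smallest unadjusted p-values belonged to genes that did not pass over all genes (adjusted p = 0.716 for each). On the LT-HSC side these included Clu, Ak1, Igf2 and Clec1a. Clu, which encodes the secreted chaperone clusterin, stood at 186 ± 6.90 CPM in LT-HSC and 0.366 ± 0.517 CPM in ST-HSC (SD, n = 2 each). Ak1, an adenylate kinase gene, had a log2 fold change of 2.17 ± 0.31 (SE), and Clec1a, a C-type lectin gene, had 1.76 ± 0.29 (SE). Igf2, the imprinted growth factor gene, had no read in ST-HSC and was at 103 and 51.2 CPM in LT-HSC 1 and 2, at least 385-fold higher against a floor of 3 reads per library, or at least 255-fold without LT-HSC 1. On the ST-HSC side were Nasp and Top2a, Mad2l1 (a spindle checkpoint gene, log2 fold change -2.68 ± 0.39 SE), Kpna2 (an importin gene, -2.22 ± 0.35 SE) and Itga2b (the gene of the platelet integrin CD41, -4.81 ± 0.74 SE).

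**Figure D2:**
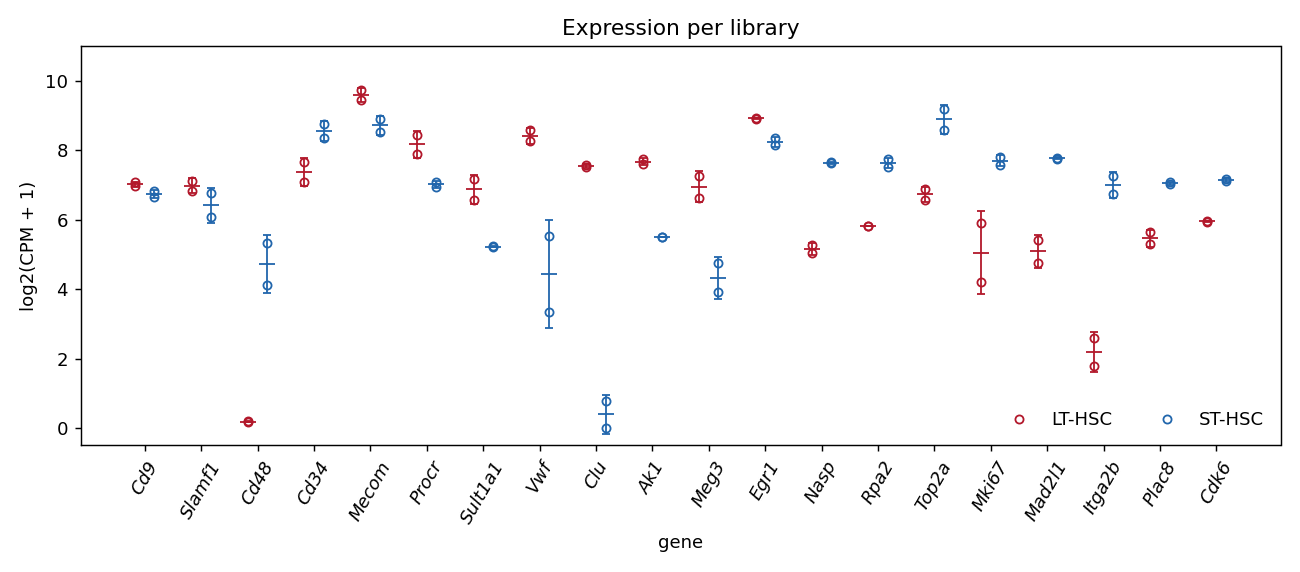
log2(CPM + 1) of 20 named genes in each library. Open circles are the 2 libraries of a group, the dash is their mean and the bar 1 SD, with LT-HSC in red and ST-HSC in blue. Cd9 lies at 129 CPM in LT-HSC and 106 CPM in ST-HSC, while Top2a lies at 106 CPM and 482 CPM. Over all genes, 0 passed the limma test at an adjusted p under 0.05.

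Lists of progenitor and blood lineage genes did not pass with all 4 libraries, and their medians moved with single libraries or filters, so the range over the alternatives stands beside each. Multipotent progenitor genes had a median of -0.11 and a mean of -0.81 over 14 members (adjusted p = 0.0795), and the median ranged from -1.06 without LT-HSC 1 to -0.07, with Plac8 at -1.58 ± 0.37 (SE) and Cdk6, a kinase gene of G1 progression, at -1.20 ± 0.32 (SE). Megakaryocyte-platelet genes had a median of 0.03 over 24 members (adjusted p = 0.536), ranging from -0.03 without ST-HSC 2 to 0.47 without LT-HSC 2. Adjusted over the list alone, 1 of them was higher and 1 lower, against 0 over all genes. The higher one, Vwf (von Willebrand factor), was at 342 ± 53.4 CPM in LT-HSC and 27.2 ± 25.6 CPM in ST-HSC (SD, n = 2 each). The lower one, Itga2b, was at 3.73 ± 1.81 CPM in LT-HSC and 128 ± 32.7 CPM in ST-HSC (SD, n = 2 each). Erythroid genes had a median of -0.10 and a mean of -0.77 (adjusted p = 0.0795), and the median ranged from -0.52 without ST-HSC 2 to -0.07, with Klf1, the erythroid transcription factor gene, at 0.215 ± 0.129 CPM in LT-HSC and 18.4 ± 12.7 CPM in ST-HSC, and Aqp1, a water channel gene, at 0.612 ± 0.865 CPM and 25.8 ± 3.04 CPM (SD, n = 2 each). Granulocyte-macrophage progenitor genes had a median of -0.04 and a mean of -0.65 (adjusted p = 0.308), and the median ranged from -0.59 without ST-HSC 2 to 0.12 without ST-HSC 1, with Mpo, the myeloperoxidase gene, at 0.0309 ± 0.0438 CPM and 15.7 ± 7.96 CPM (SD, n = 2 each). Monocyte-macrophage genes had a median of -1.02 (adjusted p = 0.131), ranging from -1.56 without ST-HSC 2 to 0.23 without LT-HSC 2, and passed without LT-HSC 1 (median -1.37, adjusted p = 0.0152) and by camera on ranks (adjusted p = 0.0401). Neutrophil genes had a median of -1.21 over 6 members (camera adjusted p = 0.253), with an estimated correlation between genes of 0.91 against the preset 0.01. The median ranged from -3.66 without ST-HSC 2 to -0.95 with no filter on low values. Between libraries of the same number the neutrophil median was -3.70 and 0.16. Lymphoid progenitor genes had a median of 0.50 (adjusted p = 0.536), ranging from -0.16 without LT-HSC 1 to 0.97 without LT-HSC 2. B cell genes had a median of -0.72 over 6 members (adjusted p = 0.362), ranging from -0.82 to -0.42 without LT-HSC 1. T and NK cell genes had a median of -2.23 over 5 members (adjusted p = 0.283), or -2.45 with Thy1, unread in LT-HSC, at its bound. The median was -1.03 without LT-HSC 1, -0.58 with no filter on low values and -4.31 on the deposited values. Endothelial and stromal genes had a median of -0.67 (adjusted p = 0.738), which ranged from -2.29 on the deposited values to 0.21 with at least 50 reads in every library of a group and was -0.08 without LT-HSC 1 and -0.01 without ST-HSC 2. For mast cell and basophil genes, with 5 members tested, the median was 0.08, or -0.18 without LT-HSC 1. Their mean was -0.05, with a test direction of higher (adjusted p = 0.846).

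Signalling, surface and regulatory lists did not pass with all 4 libraries either. Over the alternatives, the medians of 14 of the 27 lists that did not pass changed sign. Interferon response genes had a median of 0.15 over 38 members (adjusted p = 0.0641). The median ranged from 0.076 with mean log2(CPM + 1) of at least 5 to 0.39 without ST-HSC 2, and was 0.22 without LT-HSC 1. Ifi44 had a log2 fold change of 0.88 ± 0.31 (SE) and Oasl1 of 0.99 ± 0.37 (SE). Imprinted genes had a median of 0.32 over 18 members (adjusted p = 0.0658), ranging from 0.095 with mean log2(CPM + 1) of at least 5 to 0.78 without LT-HSC 2. Of their members, 2 were higher adjusted over the list alone against 0 over all genes, namely Igf2 and the long noncoding RNA gene Meg3, at 125 ± 38.6 CPM in LT-HSC and 19.9 ± 8.38 CPM in ST-HSC (SD, n = 2 each). Integrins and adhesion receptors had a median of 0.31 (adjusted p = 0.131), ranging from 0.09 without ST-HSC 2 to 0.50 without LT-HSC 2, with Itga6, the integrin alpha 6 gene, at 0.73 ± 0.21 (SE) and Jam2, a junctional adhesion molecule gene, at 15.1 and 36.3 CPM in LT-HSC 1 and 2 against no read in ST-HSC, which is at least 128-fold higher, or at least 75.4-fold without LT-HSC 2. Receptors for niche signals and cytokines had a median of 0.34 (adjusted p = 0.172), or 0.22 with either 1 of the ST-HSC libraries left out, with S1pr1, a sphingosine-1-phosphate receptor gene, at 1.75 ± 0.50 (SE). Quiescence and CDK inhibitor genes had a median of 0.13 (adjusted p = 0.180), ranging from 0.03 without LT-HSC 2 to 0.22 without ST-HSC 1, with the retinoblastoma family genes Rb1 at 0.94 ± 0.29 (SE) and Rbl2 at 0.87 ± 0.26 (SE). Tetraspanins other than Cd9 had a median of -0.02 and a mean of -0.03 with a test direction of higher (adjusted p = 0.782), and the median ranged from -0.08 without LT-HSC 1 to 0.21 without LT-HSC 2, with Tspan12 at 3.81 ± 1.06 (SE) and Cd37 at -0.88 ± 0.26 (SE). The median was 0.04 for Hox and TALE genes (adjusted p = 0.448), ranging up to 0.64, and -0.07 for TGF-beta and BMP pathway genes (adjusted p = 0.894), ranging from -0.62 without ST-HSC 2 to 0.10 without LT-HSC 1. MHC class II genes had a median of -0.01 and a mean of -0.18 with a test direction of higher (adjusted p = 0.813), and the median ranged from -0.30 without ST-HSC 2 to 0.26 without LT-HSC 1.

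Metabolic and housekeeping lists had medians near 0, whose sign changed with single libraries left out in these 5 lists. These were 0.06 for 78 cytosolic ribosomal protein genes (adjusted p = 0.453, or a median of 0.17 with adjusted p = 0.00405 without LT-HSC 2), 0.03 for 73 oxidative phosphorylation genes (adjusted p = 0.782), 0.08 for glycolysis genes (adjusted p = 0.536), 0.04 for cholesterol synthesis genes (adjusted p = 0.669) and 0.02 for heat shock genes (adjusted p = 0.676). ABC transporter and glutathione genes had a median of 0.07 and a mean of -0.02 with a test direction of higher (adjusted p = 0.782), and the median ranged from 0.01 without LT-HSC 1 to 0.15 without LT-HSC 2, with Abcg2, the side population efflux pump gene, at 0.48 ± 0.24 (SE). Between libraries numbered 1 and 2, the median was 0.19 and -0.09 for ribosomal protein, 0.11 and -0.09 for oxidative phosphorylation and 0.14 and -0.11 for heat shock genes. LT-HSC 1 had fewer reads than ST-HSC 1 and LT-HSC 2 more than ST-HSC 2, so these medians may follow library totals. Of the mitochondrially encoded genes, 10 were listed and 0 had a read, so that list could not be tested. Nothing in the labels says that the libraries of a group came from separate animals. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. The camera p-values with the preset correlation set a list's genes against all other tested genes, so their units are genes and not libraries. Floors and read counts cover counting error only, since amplified reads are not independent molecules.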

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

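The TMM factors, the deposited values as they are, the filter on mean expression and camera on ranks were chosen after seeing the data; the other settings were planned. Single genes gave 0 calls in each direction under every setting run, with 396 to 1116 genes at an unadjusted p under 0.05 and a smallest adjusted p between 0.0732 (without ST-HSC 1) and 0.9 (mean log2(CPM + 1) of at least 5). The 75 named genes kept their sign under each setting that tested them and none passed. The lists of HSC-associated, S phase and G2/M phase genes kept their calls in 16 of 18 alternatives and lost them with the estimated correlation and with fry. The immediate early genes kept theirs in 15 of 18, and lost it with no filter on low values (adjusted p = 0.104), without LT-HSC 1 (adjusted p = 0.0622) and with the estimated correlation (adjusted p = 0.592). Medians ranged from 0.34 to 0.67 for HSC-associated, -1.43 to -0.85 for S phase, -1.53 to -1.05 for G2/M phase and 0.28 to 0.46 for immediate early genes.

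Against 2 gene lists higher and 2 lower in LT-HSC, no filter gave 1 higher, an adjusted p under 0.1 gave 4 higher and 4 lower, the estimated correlation gave 0 and 0, and fry gave 1 higher and 0 lower. With the estimated correlation, camera called the S phase list in 0 of the 10 simulated runs that shifted it by -1. A call lost under that setting therefore cannot decide whether a list moved. For fry the cause was not tested. With 1 library left out there were 2 to 3 lists higher and 2 to 3 lower, and the lone library of a group was then assumed to vary like the others. Monocyte-macrophage (median -1.37) and interferon response genes (0.22) passed without LT-HSC 1, cytosolic ribosomal protein genes (0.17) without LT-HSC 2, imprinted genes (0.35) without ST-HSC 1, and neutrophil (-3.66) and interferon response genes (0.39) without ST-HSC 2. On ranks, monocyte-macrophage and histone genes passed as well. Scaling, filtering and left-out libraries put the median of all genes between -0.06 and 0.06.

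With the replicate block, 0 genes by limma (878 at an unadjusted p under 0.05) and 2 lists in each direction passed, as without it. Deviations of libraries with the same number correlated at 0.0518 across all tested genes and at 0.105 across the 7241 with mean log2(CPM + 1) of at least 5. The labels do not say that a number marks a shared animal or day. Y-linked transcripts and Tsix differed by number in the same direction in both groups (below), so a shared source per number stays open. The planned negative binomial tests were not run; limma-voom was run on the recovered reads in their place, and scaling by library totals alone is the main setting here. Fewer than 3 reads in a library, at most 0.229 CPM, cannot be told from none.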

Other observations

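The tests of expression-matched lists, other lineages, other splits and sequencing depth were chosen after the results were seen, as was the bound set on the planned fits that leave out a library. Those of gaps by read level and of reads per base were written down first, apart from a condition on Gapdh given below.

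Some genes were read in both libraries of one group and in neither of the other. With at least 100 reads in both LT-HSC libraries and none in ST-HSC there were 35 genes, and 13 the other way. The 35 hold 12 gene models without a name. Of these, Gm5156 and Gm4567 share all their values and Gm6176 and Gm6902 nearly do, so the count can hold gene copies that share reads. The genes named here were chosen after their values were seen and carry no test. The 35 include Igf2, Jam2, the growth factor gene Pdgfc (25.1 and 80.8 CPM), Mertk, a receptor gene for the uptake of dying cells (15.1 and 16.4 CPM), Clec7a, which encodes the beta-glucan receptor (29.4 and 33.8 CPM), and Smtnl1 (43.8 and 80.2 CPM). The 13 include Stil, a centriole duplication gene (26.2 and 43.9 CPM), Ska1, a kinetochore gene (8.31 and 8.63 CPM), Ly9, a relative of Cd48 and Slamf1 (11 and 52.8 CPM), and Stab2, a scavenger receptor gene (28.3 and 15.4 CPM). Splitting the same libraries by their number gave 37 such genes in all and the crossed split 19, against 48 for the real split. At an unadjusted p under 0.05, limma gave 735 genes for the split by number and 475 for the crossed split, against 814 for the real split.

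The S and G2/M phase lists were lower in LT-HSC, and a lower share of dividing cells in the CD9-high, CD34-negative gate is a candidate explanation that stays open and was not tested. A shift by uneven capture common to genes of this expression level is argued against. The higher of the 2 medians was -1.16, while the 2.5th percentile of matched lists was -0.18 for S phase and -0.23 for G2/M phase. Matched lists draw genes independently, so a capture effect that moves the list's genes together for another reason was not tested. No single library carried the fall of the lists, since the highest of the 2 medians with 1 library left out was -0.855. Dividing progenitors of another lineage, which a CD48-negative, CD150-positive gate is meant to remove, cannot be told apart from a difference in the stem cells. Neither the erythroid (camera adjusted p = 0.0795) nor the granulocyte-macrophage list (median -0.04, adjusted p = 0.308) passed. Of 16 erythroid genes, 6 lay lower in both LT-HSC libraries and 1 higher, and of 13 granulocyte-macrophage genes, 5 and 1. Cd48 had 247 and 575 reads in ST-HSC against 2 in each LT-HSC library. In CPM, Klf1 was at 27.4 and 9.43 in ST-HSC against 0.306 and 0.124 in LT-HSC, and Aqp1 at 23.7 and 28 against 1.22 and 0. Ermap was at 11.4 and 14.9 against 0.764 and 0, Mpo at 10 and 21.3 against 0 and 0.0619, and Hba-a1 at 118 and 81.3 against 67.5 and 39.6. Other lineage genes differed little, with Hbb-b1 at 130 and 118 against 119 and 108 and Car2 at 181 and 187 against 225 and 175. Lyz2 was at 146 and 140 against 153 and 146, and Prtn3 at 226 and 216 against 289 and 217. Epor and Rhag went the other way, with log2 fold changes of 1.47 and 1.60. A ceiling on reads per base, which stays open below, could hold Hbb-b1, Car2, Lyz2 and Prtn3 alike between groups. Their values therefore do not show that lineage content was alike. The real split called 4 lists and the highest other split 1, and with 1 of 3 splits giving as many, the splits are too few for a share under 0.05.

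Many genes read at 100 or more in 1 library had no read in the other library of its group, 1188 cases over both groups. Sequencing depth is argued against, because Poisson sampling predicts fewer than 1 such case. Capture of few transcripts per gene may account for the gaps. The share fell from 12.4% at 100 to under 300 reads to 1.66% at 300 to under 1000 reads and 0.0876% at 1000 reads or more. That explanation predicted a fall, but other sources of spread between libraries would give a fall too, so it does not single out capture. No biological explanation was tested.

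The most abundant genes held few reads, with 1.35% to 1.44% of a library's reads in its 10 most read genes. Actb had 8470, 8529, 8642 and 8411 reads in LT-HSC 1, LT-HSC 2, ST-HSC 1 and ST-HSC 2, and Rplp0 had 3490, 3551, 3556 and 3533, while Gapdh had 338, 340, 433 and 491. A ceiling on reads per base, such as removal of duplicate reads, could give this and would shrink folds of abundant genes, but it stays open. Where reads stay alike across libraries, as for Actb and Rplp0, CPM fall as the library total rises. The reads per exonic base exceeded by 0.1% of genes were at most 7.32 times those exceeded by 10% of genes, between the bounds of 5 and 20 set beforehand, over the 89.6% of tested genes with a length in the annotation. Loss of reads shared with gene copies also stays open. Cytosolic ribosomal protein genes had at least 5.81 times the median reads per base of all tested genes. By the rule written beforehand, this and the small share of the 10 most read genes would have argued against that loss. The bound is too low for genes this abundant, and a condition on Gapdh, absent from the rule, was added. Gapdh, which has many copies, had 0.0818 to 0.119 reads per base against medians of 0.13 to 0.177. The length of a gene joined all its annotated exons, which can exceed its main transcript and lower its reads per base. The low value of Gapdh therefore cannot decide either. No biological explanation was tested.

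Libraries numbered 1 and 2 differed in sex-linked transcripts within both groups. Uty, on the Y chromosome, was at 7.87 and 102 CPM in LT-HSC 1 and 2 and at 43.9 and 106 CPM in ST-HSC 1 and 2, and Eif2s3y at 126, 200, 67.4 and 233 CPM. Tsix, which overlaps Xist on the other strand, was at 456 and 71.0 CPM in LT-HSC and at 600 and 120 CPM in ST-HSC, where no strand setting is given and reads of both genes cannot be separated. Of 8 within-group differences in the X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, 3 were higher in library 1. LT-HSC 1 had the fewest reads but the most genes with 1 to 10 reads, 1652 against 933 to 1079 in the other libraries, and 129 of 1099 olfactory receptor genes with a read, against 18 to 53.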
